A study of Homo sapiens with 5 samples.

How the data were processed

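Gene expression was measured in 5 human muscle specimens, 2 of extraocular muscle and 3 of quadriceps femoris, with 1 array of Affymetrix design per specimen. Groups and array numbers were taken from the labels. The deposited table holds 1 intensity per probe set and array, on a linear scale, for 22215 probe sets. The tool, version and settings by which the authors made these intensities are not given in the sources used here. The values themselves were above 0 on every array, and their 2%-trimmed means lay between 796.4 and 797.7, so the arrays were on 1 common scale and were used with the deposited scaling. No detection calls were used here, so a low value could not be told from background, and no control probe sets were among the rows.

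Probe sets were named through a table of the platform's annotation, with symbols looked up by gene identifier in a RefSeq gene table of the assembly GRCh38.p14, used for names and chromosomes only. By identifier, 19022 single-symbol probe sets matched that table and 12 kept the platform's symbol, and no symbol changed. Of the probe sets, 19065 had 1 symbol, 1043 had several and 2107 had none, and only those with 1 symbol entered tests. To protect donors, 52 probe sets of XIST, TSIX and Y-linked genes were left out of every step, which left 22163. For each array the intensity plus an offset of 124.3 was taken to log2, the offset being the median over arrays of the 25th percentile. The offset makes fold changes of weakly expressed genes smaller than those of the intensities. Probe sets were kept if they reached the array's 40th percentile on at least 2 arrays, which 12810 with 1 symbol did. Each gene took the probe set with the highest mean log2 value, giving 8895 genes, 2667 of them with several probe sets. Among 115 genes selected for naming, 34 had several probe sets past the filter, and for DMD, HOXB7 and PSMB2 another probe set had the opposite sign.

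Differences between the muscles were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend, two-sided), with 1 term for the muscle and no covariate. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called higher or lower. Type of collection, autopsy or biopsy, followed the muscle in all specimens and could not enter as a covariate. Standard errors are those of the moderated fit, and SDs are over the intensities of a group. Genes were also counted, without a test, that were at least 2-fold apart in all 6 pairings of an extraocular with a limb array.

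For 30 gene lists of muscle, metabolic, developmental, stress and cell type marker genes, those with at least 5 measured genes were tested with limma's camera, which compares a list with the other genes, at a preset correlation of 0.01. The lists were: developmental, extraocular and cardiac-type myosins; adult fast-fibre and slow-fibre contractile genes; glycogen metabolism, glycolysis, oxidative phosphorylation and fatty acid genes; excitation-contraction coupling, dystrophin complex, neuromuscular junction and complement. Further lists held HOX, craniofacial and myogenic regulators, matrix, growth factors, antioxidant, proteasome, immediate early, heat shock and hypoxia genes. The marker lists were those of immune, nerve, endothelial, smooth muscle, fat, fibroblast, blood, lacrimal and ocular surface, and melanocyte and retinal cells. Camera with an estimated correlation and the rotation test fry were run beside it. Named genes were, by rule, the 12 largest rises and 12 largest falls among called genes without overlap between the muscles, the 3 members of each list with the smallest p, all measured myosin heavy chains of the first 3 lists, and DMD, UTRN, CD55 and the acetylcholine receptor subunits where measured; a further gene of the rule is not reported here. The text names those from the list part that its counts call for.

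The groups, the tests, the lists, the rule for named genes and all alternatives but 1 were fixed before the data were examined. Alternatives were quantile normalization, centring on the median, an offset 4 times smaller or larger, no filter and a filter at the 60th percentile, the mean of a gene's probe sets, leaving out each array, eBayes without a trend or robust, array weights, and a 2-fold minimum. Leaving out CKM, GAPDH and ALDOA was chosen after seeing the data. Where leaving out an array left 1 extraocular array, its spread was taken to be that of the limb arrays.

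The procedure was tested on simulated data with the 8895 genes of this comparison. It recovered 47.8% of 67 genes changed by 1 on the log2 scale, 98.5% of 67 changed by 2 and 98.5% of 66 changed by 3, with 11 false calls among 174. In simulated lists, 0 were called with none shifted, and the 1 shifted list was called. The simulated genes were drawn independently of one another, so this does not show how the list test behaves with correlated genes. Their noise was normal, with the moderated spread of the fit, so the recovery may not hold for genes of outlying spread. Tables were read with pandas 2.3.3 and figures drawn with matplotlib 3.10.9. Arrays give no counts, so precision is limited by their number.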

Results

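RNA from 2 extraocular muscle specimens and 3 quadriceps femoris specimens, called limb muscle here, was measured on oligonucleotide arrays with 22215 probe sets, 1 array per specimen. Extraocular muscles move the eye, and the quadriceps extends the knee. One extraocular label names the superior rectus and the other does not name the muscle. The arrays are called extraocular 2 and 3 and limb 5, 6 and 12, after the numbers in the labels. All extraocular specimens were labelled as collected at autopsy and all limb specimens as collected at biopsy, so the type of muscle and the type of collection could not be told apart in any comparison. The 2%-trimmed mean intensity of the arrays lay between 796.4 and 797.7. Over all probe sets, the log2 values of the extraocular arrays correlated at Pearson's r = 0.931, those of the limb arrays at 0.944 to 0.949, and those of arrays of different muscles at 0.880 to 0.913. These correlations are across probe sets, which are not independent replicates. The number of arrays limited the precision of every value.

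The comparison asked which genes differ in expression between extraocular and limb muscle. Extraocular muscle had higher signals for chromogranin B and for its own myosin heavy chain, and limb muscle for FBP2, a muscle enzyme, and for the HOX genes HOXC10 and HOXC6. Lists of nerve, complement, matrix and immediate early genes were called higher in extraocular muscle and glycogen genes lower at a preset correlation between genes, through 3 of 9, 5 of 15, 2 of 24, 5 of 19 and 3 of 15 members called. None of these lists was called with an estimated correlation (adjusted p-values 0.580 to 0.597). Of these lists, the rotation test fry called complement alone. It also called the list of developmental, extraocular and cardiac-type myosins, called higher at the preset correlation but not with an estimated one. Proteasome genes were called lower at the preset correlation and by neither other test. The matrix list also lost its call without limb 12 (median log2 change 0.39), and the immediate early list without extraocular 3 (0.34). Of 8895 genes tested with limma, 437 were higher and 322 were lower in extraocular muscle at a Benjamini-Hochberg adjusted p under 0.05, and 364 and 247 of these differed by at least 2-fold. None of the 759 genes called had overlapping values between the muscles. Among all genes tested, 40.2% had no overlap, against 20% by chance for 2 arrays against 3. All 6 pairings of an extraocular with a limb array were at least 2-fold apart for 157 genes higher and 93 genes lower in extraocular muscle.

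CHGB, the granin chromogranin B of secretory granules, was among the largest rises. Its intensity was 13861 ± 2541 (SD, n = 2) in extraocular and 353 ± 28.0 (SD, n = 3) in limb muscle, a log2 change of 4.86 ± 0.22 (SE; adjusted p = 8.13e-06). MYH13, the extraocular myosin heavy chain, reached 22032 ± 810 (SD, n = 2) against 856 ± 114 (SD, n = 3), a log2 change of 4.51 ± 0.22 (SE; adjusted p = 8.13e-06). F3, the tissue factor that starts coagulation, rose by 4.10 ± 0.28 on the log2 scale (SE; adjusted p = 9.60e-05). The rises of GRB14, an adaptor that binds the insulin receptor, OGN, a small proteoglycan of the matrix, LRTM1, and TPPP3, a tubulin-binding protein, were 12.9-fold, 12.2-fold, 9.65-fold and 8.62-fold, with adjusted p-values between 0.000163 and 0.0011. These sizes depend on the offset, since F3 had a limb mean of 53.9, below the offset of 124.3, and a value that low could not be told from background. With offsets 4 times smaller and larger the log2 changes were 5.13 and 2.64 for F3, 4.31 and 2.55 for GRB14, 4.39 and 2.41 for OGN and 3.74 and 2.03 for TPPP3. The larger offset gave 4.07 for CHGB and 2.68 for LRTM1. The 12 largest rises also held the immediate early gene FOS and the stress gene GADD45B. Also among them were CKM, GAPDH and ALDOA, which encode muscle creatine kinase and glycolytic enzymes and whose limb arrays were far apart.

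MYBPC2, the fast-fibre myosin-binding protein C, was among the largest falls, from 16940 ± 2861 (SD, n = 3) in limb to 329 ± 380 (SD, n = 2) in extraocular muscle (log2 change -5.54 ± 0.46, SE; adjusted p = 0.000326). FBP2, the muscle fructose-1,6-bisphosphatase, was at 6536 ± 1745 (SD, n = 3) and 67.1 ± 6.93 (SD, n = 2; log2 change -5.09 ± 0.26, SE; adjusted p = 9.82e-06). MYOM2, an M-band protein, was 16.6-fold lower in extraocular muscle, and CACNG1, a subunit of the muscle calcium channel, 12.1-fold lower. Without extraocular 2 the log2 changes of MYBPC2, MYOM2 and CACNG1 were -4.55, -3.46 and -2.72, and without extraocular 3 they were -6.52, -4.64 and -4.48. CA3, a cytosolic carbonic anhydrase, was 11.1-fold lower, UCP3, a mitochondrial uncoupling protein, 8.38-fold, and AMPD1, the muscle AMP deaminase, 7.21-fold lower. PTPN3, a tyrosine phosphatase, fell from 4150 ± 1571 (SD, n = 3) to 285 ± 39.0 (SD, n = 2). FBP2 lay below the offset in extraocular muscle. With offsets 4 times smaller and larger, the log2 changes were -6.03 and -3.61 for FBP2 and -6.14 and -4.47 for MYBPC2. The larger offset gave -3.41, -2.72, -2.29 and -2.52 for MYOM2, CACNG1, UCP3 and PTPN3. Among the 12 largest falls were also HOXC10, the slow-fibre proteins MYL3 and TNNI1, and RHOBTB1. Of the 24 genes with the largest changes, 16 were called whichever array was left out. MYL3 and TNNI1 lost the call without limb 6, at log2 changes of -3.07 and -2.92 (-1.82 and -1.79 without extraocular 2, -4.33 and -3.94 without extraocular 3), and RHOBTB1 without extraocular 2, at -2.60.

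**Figure D1:**
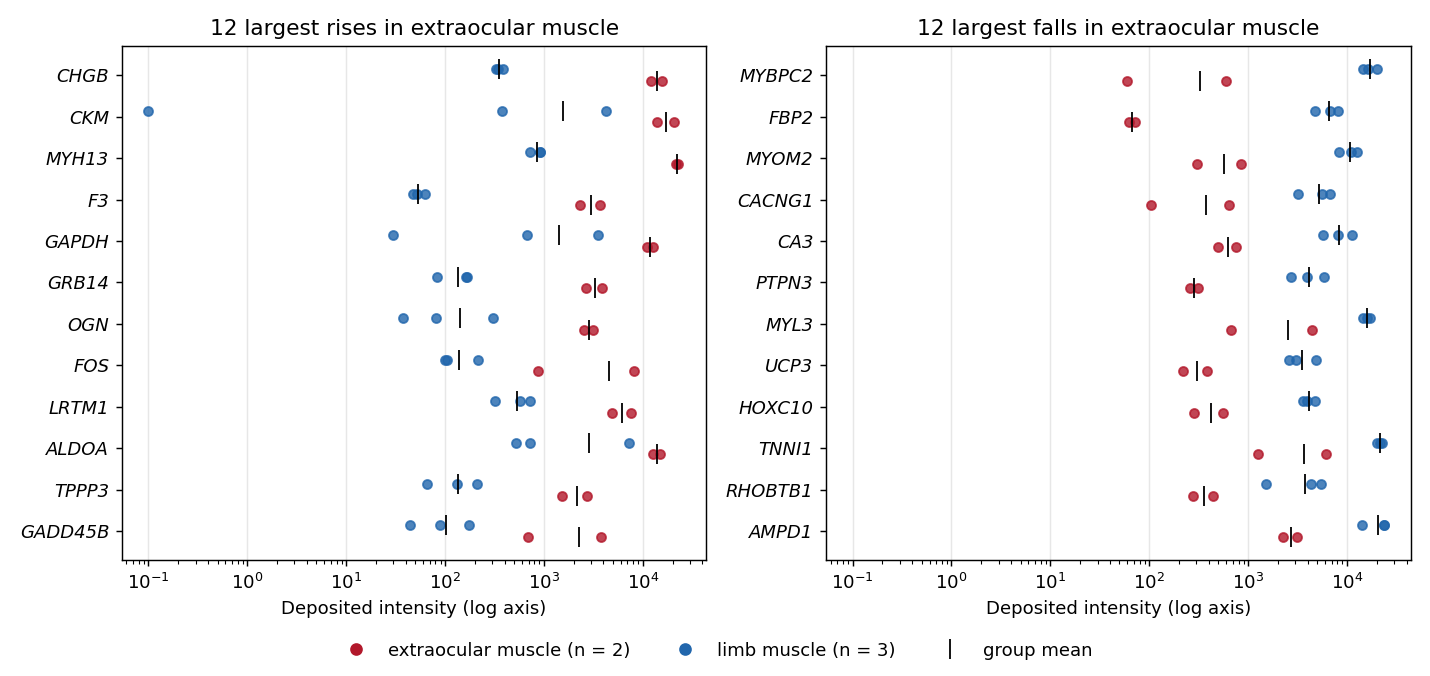
Deposited intensity on a log axis of the 12 genes with the largest rise (left) and the 12 with the largest fall (right) in extraocular muscle among genes called and without overlap between the muscles. Red points are the extraocular arrays (n = 2), blue points the limb arrays (n = 3) and vertical lines the group means. MYH13 was at 22032 against 856, and the limb values of CKM ran from 0.1 to 4270.6.

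CKM, GAPDH and ALDOA were called higher in extraocular muscle, with log2 changes of 4.72 ± 1.09, 3.96 ± 0.96 and 3.12 ± 0.82 (SE) and adjusted p-values of 0.0292, 0.0341 and 0.0445. Their limb arrays were far apart. CKM was at 0.1, 374.3 and 4270.6 on limb 5, 6 and 12, and ALDOA at 730.0, 518.0 and 7263.9. For all 6 probe sets of these genes, limb 12 was the highest of the limb arrays. The extraocular arrays were apart too on GAPDH probe sets not used for its value. Such a probe set was at 9930.1 and 2648.1 on extraocular 2 and 3. Another was at 7368.7 and 1837.9, and there limb 12, at 2768.8, exceeded extraocular 3. The call of CKM ended without extraocular 2 (log2 change 4.43), without extraocular 3 (5.01) and without limb 6 (4.53). GAPDH lost its call without the same arrays (3.86, 4.06 and 2.80), and ALDOA without those (3.23, 3.00 and 2.46) and without limb 5 (2.67). Without limb 12 the log2 changes of CKM, GAPDH and ALDOA were 6.10, 5.09 and 4.22, and that of CKM was 3.53 without limb 5. With all arrays, the 3 calls also ended after centring on the median (4.68, 3.92 and 3.08), with an offset 4 times smaller (5.48, 4.47 and 3.25; CKM and GAPDH were at 3.77 and 3.18 with one 4 times larger), with no filter, and in eBayes without a trend or robust.

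**Figure D2:**
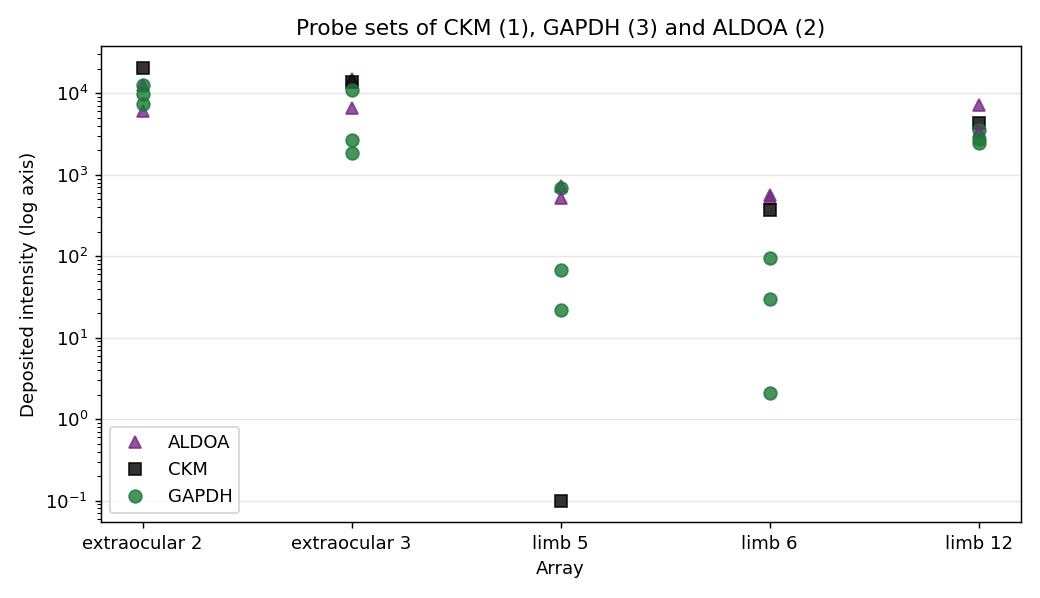
Deposited intensity, on a log axis, of the 6 probe sets of CKM (1), GAPDH (3) and ALDOA (2) on each of the 5 arrays. Each point is 1 probe set on 1 array, and on limb 12 each lies above its values on limb 5 and limb 6.

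Genes were then grouped in 30 lists fixed before the data were examined, of which 29 had at least 5 measured genes and were tested with camera, a test of whether a list differs from the other genes measured. It called 13 lists, 7 higher and 6 lower in extraocular muscle, with a preset correlation between genes. With a correlation estimated from the arrays, camera called 0 of the 29, with 1 at an unadjusted p under 0.05 and a lowest adjusted p of 0.580. The rotation test fry, which asks whether the genes of a list move one way, called 3, and 2 of these were among the 13. These 2 were the developmental, extraocular and cardiac-type myosins and complement (fry adjusted p-values 0.0132 and 0.0181). The nerve, matrix, immediate early and glycogen lists had fry adjusted p-values of 0.151, 0.440, 0.336 and 0.0873. Called members outside the rule for named genes are named too, and were chosen after their values were seen: LDHB, PKM, ACTC1, MYOZ2, ANKRD2, ASPH, PRKAR1A, C3, C1R, PSMB5, EGR3 and KLF4.

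Developmental, extraocular and cardiac-type myosins were higher in extraocular muscle as a list (7 genes, median log2 change 1.15, adjusted p = 0.0155; adjusted p = 0.580 with an estimated correlation). MYH13 and MYL4, an atrial and embryonic light chain, rose, and 5 members did not pass. Adjusted over the list alone, 3 rose (with MYH3) and 1 fell (MYH7B). With an offset 4 times larger the list stayed called, at a median of 0.55. MYL4 was 2.22-fold higher (adjusted p = 0.026), a call that ended without extraocular 2, extraocular 3, limb 6 or limb 12, at log2 changes of 0.97 to 1.25. Values that did not pass were 1.31 for MYH3, the embryonic heavy chain, 0.62 for MYH8, the perinatal one, 1.72 for MYH15, 0.11 for MYH6 and -0.61 for MYH7B. MYH15 was at a log2 change of 3.32 without extraocular 3 and 0.12 without extraocular 2. Without extraocular 3, MYH6 and MYH8 turned to -0.88 and -0.03 (1.10 and 1.28 without extraocular 2), and MYH6 was also below 0 without limb 5 (-0.13) or limb 6 (-0.12). The list was not called with the stricter filter on low signals (median 0.62; adjusted p = 0.0609, range over the alternatives 0.00581 to 0.580).

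Adult fast-fibre contractile genes were lower as a list (15 genes, median -0.18, adjusted p = 0.0419; adjusted p = 0.597 with an estimated correlation), a median that turned to 0.06 under quantile normalization and to 0.04 without limb 12, where the list was not called. MYBPC2 and MYOM2 fell, 13 members did not pass, and adjusted over the list alone the counts were 0 higher and 2 lower. The fast heavy chains MYH1 and MYH2 were at 20828 ± 3970 and 19574 ± 1064 (SD, n = 2) in extraocular and at 20429 ± 782 and 23983 ± 2270 (SD, n = 3) in limb muscle, with adjusted p-values of 0.980 and 0.482. These intensities lay near the highest of the arrays (25165.6 to 32302.4). A difference compressed at the top of the scale could therefore have been missed, which was not tested. MYH4 had a log2 change of 1.27 (adjusted p = 0.290), which was 2.60 without extraocular 3 and turned to -0.06 without extraocular 2. The list also lost its call without limb 5 (median -0.25), after centring (-0.22), with the stricter filter and with the mean of probe sets (-0.18 for each). Slow-fibre and cardiac contractile genes were not called as a list (13 genes, median -0.28, adjusted p = 0.0661). ACTC1, cardiac actin, rose, MYL3, TNNI1, CSRP3, MYOZ2 and ANKRD2 fell and 7 did not pass, and adjusted over the list alone 2 rose and 5 fell. ACTC1 was at 14639 ± 1706 (SD, n = 2) against 3710 ± 2411 (SD, n = 3; adjusted p = 0.0144). CSRP3, a Z-disc protein, fell from 19519 ± 2936 (SD, n = 3) to 4586 ± 3560 (SD, n = 2; adjusted p = 0.0116), a call lost without limb 6 (log2 change -2.24, with -1.43 without extraocular 2 and -3.15 without extraocular 3). ACTC1 and MYOZ2 lost theirs without extraocular 2 (2.00 and -1.09), limb 6 (1.97 and -1.65) or limb 12 (1.79 and -1.51), and ANKRD2 without extraocular 3 (-1.79) or limb 6 (-1.86), while it was at -3.29 without extraocular 2. With all arrays, the call of ANKRD2 also ended with an offset 4 times larger (-1.66), with no filter, and in eBayes without a trend or robust. MYH7, the slow heavy chain, was at a log2 change of 0.78 (adjusted p = 0.517), which turned to -0.36 without extraocular 3 and was 1.92 without extraocular 2. The median of this slow list relative to the limb mean was -0.86 on extraocular 2 and 0.01 on extraocular 3.

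Genes of glycogen metabolism were lower in extraocular muscle as a list (15 genes, median -0.45, adjusted p = 0.000241; adjusted p = 0.580 with an estimated correlation). GYG1, the glycogenin that primes glycogen, fell 2.52-fold, PPP1R1A, an inhibitor of protein phosphatase 1, 4.16-fold, and PHKG1, the catalytic subunit of muscle phosphorylase kinase, 2.36-fold (adjusted p-values 0.011, 0.0114 and 0.0116). The other 12 members did not pass, and adjusted over the list alone 6 fell and 0 rose. The calls of GYG1, PPP1R1A and PHKG1 ended without extraocular 2 (log2 changes -1.20, -1.36 and -1.25), and those of GYG1 and PPP1R1A also without limb 12 (-1.24 and -1.91). Without extraocular 3 the log2 change of PPP1R1A was -2.75 and the list's median -0.71.

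Glycolysis genes were not called as a list (16 genes, median -0.27, adjusted p = 0.136). The list, as fixed, also held FBP2 and GPD1, which are not enzymes of the glycolytic chain itself. GAPDH, ALDOA and LDHB rose, FBP2, GPD1, PGAM2 and PKM fell and 9 did not pass, and adjusted over the list alone the counts were also 3 and 4. LDHB, the heart-type subunit of lactate dehydrogenase, was at 18567 ± 48.9 (SD, n = 2) against 8048 ± 2275 (SD, n = 3). FBP2 was at a log2 change of -5.09, which was -6.03 and -3.61 with offsets 4 times smaller and larger. GPD1, a glycerol phosphate dehydrogenase, and PGAM2, the muscle phosphoglycerate mutase, were 3.80-fold and 3.52-fold lower. GPD1 lost its call without extraocular 2 (log2 change -2.18), extraocular 3 (-1.68) or limb 12 (-1.73), and PGAM2 without extraocular 2 (-1.21) or limb 6 (-1.72), while it was at -2.43 without extraocular 3. LDHB lost its call without any array but limb 5 (1.23 to 1.40), and PKM, a pyruvate kinase, with any single array left out (-0.67 to -1.04).

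Nuclear-encoded genes of oxidative phosphorylation were not called as a list (39 genes, median -0.19, adjusted p = 0.165). Its median relative to the limb mean was -0.36 on extraocular 2 and 0.07 on extraocular 3. Its counts were 2 higher, 0 lower and 37 not passed, and NDUFA5 was the 1 gene higher adjusted over the list alone. The higher ones were the complex I subunits NDUFA5 and NDUFB8, 1.99-fold and 1.97-fold, and both calls ended with any single array left out (log2 changes 0.93 to 1.05 and 0.84 to 1.14). Another NDUFA5 probe set was at 0.006 and other NDUFB8 probe sets at 0.30 and 0.47. With the mean of probe sets both calls ended (0.50 and 0.59). Genes of fatty acid uptake and oxidation were called lower (20 genes, median -0.47, adjusted p = 0.0419; adjusted p = 0.673 with an estimated correlation), with 1 higher, 1 lower and 18 not passed, and 1 and 1 adjusted over the list alone. UCP3 was the member that fell. DECR1, a reductase needed to oxidise unsaturated fatty acids, was 2.20-fold higher, and lost its call without extraocular 3 (log2 change 0.90), limb 5 (1.04) or limb 6 (1.10). The fatty acid list rested on extraocular 2: without that array its median was 0.10 and the direction of the test turned, and without extraocular 3 it was -1.002. Without limb 6 or limb 12 the list was not called either (median -0.41 for each). With all arrays, it was not called under quantile normalization (-0.43), after centring (-0.51), with the stricter filter (-0.47) or with the mean of probe sets (-0.29).

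Genes of excitation-contraction coupling were not called as a list (15 genes, median -0.16, adjusted p = 0.0753). Of its members, ASPH was higher, 3 were lower and 11 did not pass, with counts of 1 and 3 adjusted over the list alone too. PLN, phospholamban, which restrains the calcium pump of slow and cardiac muscle, fell from 12441 ± 1081 (SD, n = 3) to 2751 ± 1337 (SD, n = 2; adjusted p = 0.00327). CACNG1 and CACNA1S, the pore subunit of the same channel, were the other members that fell, CACNA1S by 2.50-fold. CACNG1 was at a log2 change of -2.72 without extraocular 2 and -4.48 without extraocular 3, and also at -2.72 with an offset 4 times larger. The call of CACNA1S ended without extraocular 2, limb 5, limb 6 or limb 12 (log2 changes -0.97 to -1.49). ASPH, whose locus encodes the junctional protein junctin, was 1.82-fold higher and lost its call with any single array left out (0.70 to 1.03).

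Dystrophin complex and sarcolemma genes were lower as a list (16 genes, median -0.50, adjusted p = 0.0397; adjusted p = 0.580 with an estimated correlation). Here 1 rose, 3 fell and 12 did not pass, and adjusted over the list alone 2 rose and 4 fell. CAPN3, the muscle calpain, fell 3.02-fold (adjusted p = 0.00864), SGCA, alpha-sarcoglycan, 2.35-fold, and DYSF, dysferlin of membrane repair, 2.08-fold. UTRN, the dystrophin homologue utrophin, rose from 571 ± 55.5 (SD, n = 3) to 1125 ± 126 (SD, n = 2; adjusted p = 0.0445). DMD, dystrophin itself, was at 2729 ± 793 (SD, n = 2) and 3584 ± 489 (SD, n = 3; adjusted p = 0.389), and other DMD probe sets had the opposite sign. The call of UTRN ended with any single array left out (log2 changes 0.74 to 0.95). CAPN3 lost its call without extraocular 2 (-1.24), SGCA without extraocular 2, limb 5 or limb 6 (-0.97 to -1.12), and DYSF without any of the arrays but limb 12 (-0.93 to -1.06). The list itself lost its call without extraocular 2 (median -0.34) or limb 5 (-0.49), and its median was -0.33 without limb 12. With all arrays, its call also ended under quantile normalization (-0.53), after centring (-0.54) and with the stricter filter (-0.50).

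At the neuromuscular junction, 3 genes rose, 1 fell and 10 did not pass, and adjusted over the list alone 4 rose and 1 fell. The list was not called (14 genes, median 0.23, adjusted p = 0.269), and its median was 0.42 on extraocular 2 and -0.03 on extraocular 3 relative to the limb mean. CHRNA1, the alpha subunit of the muscle acetylcholine receptor, rose from 1073 ± 245 (SD, n = 3) to 3134 ± 700 (SD, n = 2; adjusted p = 0.0108). RAPSN, rapsyn, which clusters that receptor, fell from 639 ± 65.6 (SD, n = 3) to 122 ± 73.4 (SD, n = 2; adjusted p = 0.0108). ETV5, a transcription factor of the synaptic region, rose 2.69-fold (adjusted p = 0.0168), and PRKAR1A, a regulatory subunit of protein kinase A, 2.09-fold. Other receptor subunits did not pass: CHRNB1 at a log2 change of -0.14, CHRNE, the adult epsilon subunit, at -0.39, and CHRNG, the fetal gamma subunit, at 0.10 (-0.07 without extraocular 2 or limb 12). CHRNA1 lost its call without extraocular 2 (1.23) or limb 6 (1.28), RAPSN without limb 12 (-1.66; it was at -0.88 with an offset 4 times larger), and ETV5 without extraocular 2 (0.97), limb 6 (1.49) or limb 12 (1.38). The other ETV5 probe sets were at 0.32 and 0.18, and with the mean of probe sets its call ended (0.64). PRKAR1A lost its call without any array but extraocular 3 (0.77 to 1.19).

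Complement genes and their regulators were higher in extraocular muscle as a list (15 genes, median 0.87, adjusted p = 0.00042; adjusted p = 0.580 with an estimated correlation). Of these, 5 rose, 0 fell and 10 did not pass, and adjusted over the list alone 9 rose. C1S, a protease of the classical pathway, rose from 1414 ± 285 (SD, n = 3) to 5640 ± 1009 (SD, n = 2; adjusted p = 0.00293). CLU, clusterin, and SERPING1, the C1 inhibitor, were 3.05-fold and 2.08-fold higher, and C3 and C1R 2.04-fold and 1.83-fold. CD55, decay-accelerating factor, which limits complement on cell surfaces, was at 847 ± 203 (SD, n = 2) and 995 ± 285 (SD, n = 3; adjusted p = 0.749), a log2 change of -0.19 that turned to 0.03 without extraocular 2. Both extraocular arrays exceeded every limb array for 11 of the 15 genes. CLU lost its call without extraocular 2 (log2 change 1.32), and SERPING1 without extraocular 2 (0.95), limb 6 (1.03) or limb 12 (0.97). C3 lost its call without any array but limb 5 (0.83 to 1.07), and C1R with any single array left out (0.76 to 1.001). Fibroblast, nerve and endothelial markers moved in the same direction, with the values given with those lists.

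HOX and hindlimb-position transcription factors were lower as a list (9 of 25 listed genes measured, median -0.34, adjusted p = 0.0306; adjusted p = 0.580 with an estimated correlation). HOXC10 fell from 4127 ± 592 (SD, n = 3) to 418 ± 192 (SD, n = 2; adjusted p = 0.000482), and HOXC6 from 1498 ± 220 (SD, n = 3) to 220 ± 125 (SD, n = 2; adjusted p = 0.00227). Their log2 changes were -3.01 and -2.28, and -2.34 and -1.48 with an offset 4 times larger. The other 7 did not pass, and adjusted over the list alone 2 fell and 0 rose. The list lost its call without extraocular 3 (median -0.43) or limb 6 (-0.34), and with the mean of probe sets (-0.30). Craniofacial and periocular transcription factors were not called by camera (9 of 21 measured, median 0.42, adjusted p = 0.527), and none of the 9 passed over all genes or adjusted over the list alone. By fry this list had an adjusted p of 0.0132. The members with the smallest p were EYA4, EYA2 and LHX2, at log2 changes of -0.98, 1.18 and 1.15. Myogenic regulators and satellite cell markers were not called (16 genes, median -0.03, adjusted p = 0.603), with 1 higher and 15 not passed, and 1 adjusted over the list alone. VCAM1, an adhesion molecule also found on activated endothelium, was the 1 that rose (2.26-fold, adjusted p = 0.0196), and it lost the call without extraocular 2 (log2 change 1.07), limb 6 (1.28) or limb 12 (1.04).

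Markers of Schwann cells and nerve were higher in extraocular muscle (9 genes, median 1.65, adjusted p = 0.000154; adjusted p = 0.580 with an estimated correlation). All 9 had changes above 0, 3 rose and 6 did not pass, and adjusted over the list alone 7 rose. The filter on low signals favours such signs, since 3 of the 9 reached its level on limb arrays. Without a filter 12 markers were measured. Of these, 8 were higher and 1 was lower on both extraocular arrays than on every limb array. NEFL and PRX, with changes above 0, overlapped between the muscles. NEFL was at 5106.6 on extraocular 2 but at 79.4 on extraocular 3, below the limb arrays (211.7 to 321.8). CDH19, a cadherin of Schwann cells, rose from 102 ± 73.3 (SD, n = 3) to 891 ± 145 (SD, n = 2; adjusted p = 0.00843). S100B and SOX10, also Schwann cell genes, rose by 2.68 and 1.79 on the log2 scale. The limb means of CDH19 and S100B (30.7) lay below the offset, so these sizes depend on it. With offsets 4 times smaller and larger, CDH19 was at 2.98 and 1.21 and S100B at 3.84 and 1.43, and SOX10 was at 1.08 with the larger. Another SOX10 probe set was at 0.02, and the call of SOX10 ended with the mean of probe sets (0.90) and with no filter. The list's median relative to the limb mean was 2.42 on extraocular 2 and 1.13 on extraocular 3. Calls of CDH19, S100B and SOX10 ended without extraocular 2 (log2 changes 2.07, 1.77 and 1.15; S100B was at 3.59 without extraocular 3), and those of S100B and SOX10 also without limb 6 (2.70 and 1.95) or limb 12 (2.63 and 1.66).

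Extracellular matrix genes were higher as a list (24 genes, median 0.70, adjusted p = 0.00212; adjusted p = 0.597 with an estimated correlation), although 2 rose and 22 did not pass. Adjusted over the list alone, 3 rose (with FN1, called over all genes without limb 5 at a log2 change of 1.73) and 0 fell. ELN, elastin, rose 5.92-fold (adjusted p = 0.00494), and LUM, lumican, 6.50-fold (adjusted p = 0.0225). ELN was at a log2 change of 1.64 with an offset 4 times larger and 1.61 with the mean of probe sets. The median of the list was 0.77 on limb 5 and -0.63 on limb 12 relative to the limb mean, a wider spread than the change between the muscles, and without limb 12 the list was not called (median 0.39) while without limb 5 its median was 1.17. Without extraocular 2 the median was 0.42. Markers of fibroblasts and tendon were higher (12 genes, median 0.58, adjusted p = 0.00969; adjusted p = 0.597 with an estimated correlation), with 3 higher, 0 lower and 9 not passed, and 3 higher adjusted over the list alone. PDGFRA, a receptor of interstitial fibroblasts, and MFAP5, a protein of microfibrils, were 2.76-fold and 2.64-fold higher, and LUM was the other. This list lost its call without limb 12 (median 0.48). Its median relative to the limb mean was 0.38 on limb 5 and -0.28 on limb 12, also a wider spread than its change. Calls of ELN, LUM and PDGFRA ended without extraocular 2 (log2 changes 1.89, 2.07 and 1.18; ELN and LUM were at 3.24 and 3.33 without extraocular 3), those of LUM and PDGFRA also without limb 6 (2.73 and 1.38) or limb 12 (2.11 and 1.37), and that of MFAP5 without any array but limb 5 (1.03 to 1.57).

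Growth factors and their binding proteins were not called as a list (17 genes, median 0.23, adjusted p = 0.0526). IGFBP6, which binds IGF2, rose from 1338 ± 341 (SD, n = 3) to 7220 ± 667 (SD, n = 2; adjusted p = 0.00126), IGFBP4 rose 2.43-fold and FGF2 2.47-fold. The other 14 did not pass, and adjusted over the list alone 4 rose (with PDGFA). IGFBP4 lost its call without limb 6 (log2 change 1.27) and FGF2 without any array but limb 5 (1.26 to 1.40). Endothelial markers were higher (12 genes, median 0.39, adjusted p = 0.0249; adjusted p = 0.597 with an estimated correlation) with none of the 12 passing over all genes or adjusted over the list alone, and the list lost its call without extraocular 3 (median 0.44) or limb 12 (0.31). The median of the endothelial list relative to the limb mean was 0.26 on limb 5 and -0.24 on limb 12, a wider spread than its change. Smooth muscle and pericyte markers (12 genes, median 0.19, adjusted p = 0.387) and immune cell markers (18 genes, median 0.27, adjusted p = 0.131) were not called, and no member of either passed over all genes or adjusted over the list alone. Adipocyte markers were not called (10 genes, median 0.15, adjusted p = 0.871; the mean was -0.01), with a median of -0.21 on extraocular 2 and 0.49 on extraocular 3 relative to the limb mean. GPD1 fell and 9 did not pass, and adjusted over the list alone 1 rose (CFD, called over all genes without limb 5 at a log2 change of 1.94) and 1 fell. Blood cell markers were not called (7 genes, median -0.11, adjusted p = 0.527; 0.02 on extraocular 2 and -0.29 on extraocular 3), with HBD, a globin, lower at 94.8 ± 0.212 (SD, n = 2) against 572 ± 301 (SD, n = 3; adjusted p = 0.0371), and 1 lower adjusted over the list alone. Its call ended without any array but limb 5 (log2 changes -1.26 to -1.57) and with an offset 4 times larger (-0.81). Markers of melanocytes and retina were not called (7 genes, median -0.02, adjusted p = 0.401). SAG, the retinal arrestin, was lower at 116 ± 15.6 (SD, n = 2) against 712 ± 409 (SD, n = 3; adjusted p = 0.0261), also the 1 gene adjusted over the list alone, and it lost its call without any array but limb 12 (-1.32 to -1.80), with -0.93 at an offset 4 times larger. Lacrimal gland and ocular surface markers had 4 measured genes and were not tested as a list; their median was 0.26 (0.57 on extraocular 2 and -0.08 on extraocular 3) and none passed over all genes or adjusted over the list alone.

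Immediate early and stress genes were higher in extraocular muscle as a list (19 genes, median 1.39, adjusted p = 0.000225; adjusted p = 0.597 with an estimated correlation), with 5 higher, 0 lower and 14 not passed, and 9 higher adjusted over the list alone. FOS was at 4534 ± 5184 (SD, n = 2) against 140 ± 64.5 (SD, n = 3; adjusted p = 0.0154), and was 867.8 on extraocular 2 and 8199.5 on extraocular 3. GADD45B and GADD45A, induced by DNA damage and other stress, were 8.12-fold and 6.42-fold higher, and the transcription factors EGR3 and KLF4 2.62-fold and 3.31-fold. The list's median relative to the limb mean was 0.34 on extraocular 2 and 2.24 on extraocular 3, and without extraocular 3 the list was not called (median 0.34; adjusted p = 0.539, range over the alternatives 3.20e-19 to 0.597). Without extraocular 3 the log2 changes of FOS, GADD45B and GADD45A were 1.94, 1.89 and 1.70, and without extraocular 2 they were 5.004, 4.15 and 3.67. GADD45B lost its call without extraocular 3, as it did without limb 6 (2.99), while FOS and GADD45A lost theirs without limb 6 (3.38 and 2.81) or limb 12 (3.66 and 2.49). With an offset 4 times larger FOS, GADD45B and GADD45A were at 2.44, 1.92 and 1.92, and GADD45B was at 3.76 with one 4 times smaller and 2.12 with the mean of probe sets. EGR3 lost its call without any array but extraocular 2 (0.90 to 1.56), and KLF4 without any array but limb 5 (1.22 to 2.24).

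Proteasome and atrophy genes were lower as a list (20 genes, median -0.53, adjusted p = 0.000225; adjusted p = 0.580 with an estimated correlation). Of these, 4 fell, 0 rose and 16 did not pass, and adjusted over the list alone 6 fell. PSMC4, an ATPase of the proteasome's regulatory particle, fell from 958 ± 87.6 (SD, n = 3) to 297 ± 26.8 (SD, n = 2; adjusted p = 0.0081), and PSMD4, its ubiquitin receptor, fell 2.22-fold. PSMB2, a core subunit, fell 1.80-fold, while another of its probe sets had a log2 change of 0.29, and PSMB5 fell 1.81-fold. PSMD4 lost its call without extraocular 2 (log2 change -0.84), limb 6 (-1.19) or limb 12 (-1.14), and PSMB2 and PSMB5 with any single array left out (-0.79 to -0.90 and -0.69 to -1.02).

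Heat shock and metallothionein genes were not called (16 genes, median -0.17, adjusted p = 0.736; -0.33 on extraocular 2 and 0.10 on extraocular 3), with 1 higher, 1 lower and 14 not passed, and 1 and 1 adjusted over the list alone. The chaperone HSPH1 rose 2.21-fold and the small heat shock protein HSPB1 fell 2.28-fold (adjusted p-values 0.016 and 0.0229). Both lost the call without extraocular 2 (log2 changes 1.06 and -0.90) or limb 12 (1.09 and -1.27), and HSPB1 also without limb 6 (-1.24). Hypoxia-responsive genes were not called (14 genes, median 0.05, adjusted p = 0.437; -0.12 on extraocular 2 and 0.19 on extraocular 3), with 3 higher, 0 lower and 11 not passed, and 3 higher adjusted over the list alone. NDRG1 rose from 1620 ± 114 (SD, n = 3) to 4747 ± 740 (SD, n = 2; adjusted p = 0.00509), and the glucose transporters SLC2A1 and SLC2A3 rose 2.62-fold and 3.69-fold. SLC2A1 lost its call without extraocular 2 (1.03), limb 6 (1.42) or limb 12 (1.23), and SLC2A3 without extraocular 3 (1.16), limb 6 (1.56) or limb 12 (2.16), with 2.61 without extraocular 2. It also lost its call with an offset 4 times smaller (2.52), and was at 1.05 with one 4 times larger. Antioxidant genes were not called (18 genes, median 0.03, adjusted p = 0.506), with PRDX6, a peroxiredoxin, 1.87-fold lower, 17 not passed, and 1 lower adjusted over the list alone. The call of PRDX6 ended without any array but extraocular 3 (log2 changes -0.73 to -0.95).

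**Figure D3:**
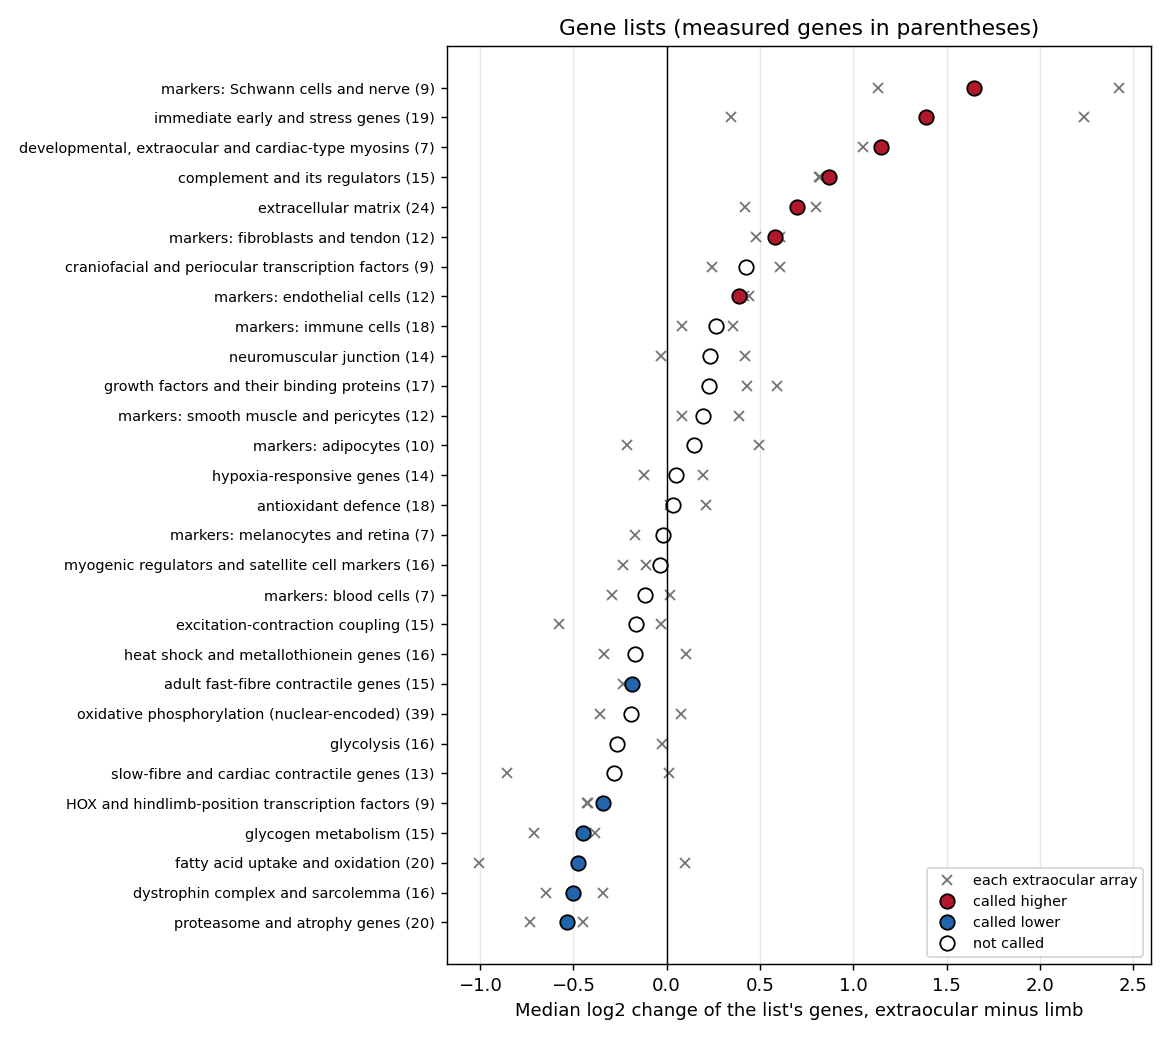
Median log2 change, extraocular minus limb, of the measured genes of each of the 29 lists tested, with the number of genes in parentheses. Filled circles are lists called higher (red) or lower (blue) by camera with its preset correlation, open circles are lists not called, and crosses are the median on each extraocular array relative to the limb mean. The crosses of the immediate early list lie at 0.34 and 2.24, and those of the nerve list at 1.13 and 2.42.

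Significance refers to limma's moderated test with an intensity trend, and p-values measure the spread between these samples, since no label says that each came from a separate donor. The number of genes called was 264 without extraocular 2, 217 without limb 6 and 270 without limb 12, against 759 with all arrays. Of 70 named genes called, 11 lost the call after centring on the median: CKM, GAPDH, ALDOA, NDUFB8, DECR1, CACNA1S, PRDX6, PSMB2, HSPB1, SLC2A3 and UTRN. DYSF and SLC2A3 lost it under quantile normalization, and 2, FGF2 and HBD, with the stricter filter. With no filter 16 genes lost it: CKM, GAPDH, ALDOA, PGAM2, NDUFB8, CACNA1S, SGCA, LUM, PRDX6, HSPB1, SLC2A3, SOX10, MFAP5, HBD, SAG and UTRN. With the mean of probe sets 8 lost it (GAPDH, NDUFA5, NDUFB8, ETV5, PRDX6, PSMB2, SOX10 and UTRN), and the log2 changes of GADD45B and ELN were 2.12 and 1.61. An offset 4 times smaller moved the fold of 11 of the 70 by over 1.5 times and ended the calls of CKM, GAPDH, ALDOA and SLC2A3, and one 4 times larger moved 28 and ended the call of HBD. Without a trend 12 calls ended (CKM, GAPDH, ALDOA, NDUFB8, CACNA1S, DYSF, SGCA, PRDX6, PSMB2, SLC2A3, MFAP5 and UTRN). With robust eBayes 6 ended (among them FOS, MYL3 and LUM) and with array weights 4. Of the genes named outside the rule, PKM, ASPH, C3, C1R and KLF4 lost their calls under both other scalings and LDHB, PRKAR1A, PSMB5 and EGR3 after centring, and these 9 and ANKRD2 lost them with no filter. Without a trend PKM, ANKRD2, ASPH, PRKAR1A, C3, C1R, PSMB5 and KLF4 lost them. With array weights PKM, ASPH, C3, C1R, PSMB5 and KLF4 did, and with the mean of probe sets PKM, ASPH, PRKAR1A and KLF4. KLF4 and ANKRD2 lost them with robust eBayes, PKM with an offset 4 times smaller and ANKRD2 with one 4 times larger.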

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

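The alternative that left out CKM, GAPDH and ALDOA was chosen after seeing the data. No paired analysis was possible because the labels do not say which specimens, if any, share a donor. A covariate for RNA quality from control probe sets was not run, since these were not among the rows used here. Counts of called genes stayed within 1.5 times the reported ones under the alternatives that kept all arrays, except that 212 genes, not 322, were lower with no filter, where more genes were tested (11939 against 8895). Scaling kept the share of higher genes near 57.6% (56.7% under quantile normalization, 57.1% after centring). With 4 times the offset, 70 genes were higher and 40 lower by at least 2-fold in all pairings, since a larger offset shrinks fold changes. Lists called lower numbered 3, not 6, under quantile normalization, after centring and with the mean of probe sets, and 2 with the stricter filter. With that filter the HOX list had too few measured genes to be tested. The cause of the other losses was not tested. With an estimated correlation 0 lists were called higher and 0 lower, with 1 at an unadjusted p under 0.05; fry called 3 higher and 0 lower. The cause of either was not tested.

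With single arrays left out, called genes ran from 123 to 400 higher and from 94 to 286 lower, with fewer arrays in each fit. With fewer pairings left, genes at least 2-fold apart in all of them ran from 186 to 364 higher and from 125 to 295 lower, and called lists from 4 to 8 higher and from 4 to 9 lower. The fatty acid list reversed without extraocular 2, with a median of 0.0977 (adjusted p = 0.483, range over the alternatives 2.80e-06 to 0.673), and over the fits without an array its median ran from -1.002 to 0.0977; the cause was not tested. Of 115 named genes 70 were called, 22 of them in all 5 fits without an array, and no called named gene changed sign under any alternative. Calls lost were 38 without extraocular 2, 17 without extraocular 3, and 11, 37 and 28 without limb 5, 6 and 12. Without a detection call, signal over background limits what low intensities can show.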

Other observations

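The tests of saturated signals, of a joint rise of glycolysis genes, of single immediate early genes, of a lower share of muscle fibres and of more nerve tissue were chosen only after the results were seen. The genes of the next paragraph were chosen after their values were seen, and each was called in limma whichever array was left out and under both other scalings, unless stated.

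Several genes in none of the fixed lists differed strongly between the muscles. MYOC, myocilin of the trabecular meshwork, was at 5772 ± 2058 (SD, n = 2) against 1033 ± 265 (SD, n = 3; adjusted p = 0.00235). CYP1B1, a cytochrome P450 linked to eye development, was 7.46-fold higher, and the secreted Wnt antagonists FRZB and SFRP4 were 8.06-fold and 4.94-fold higher, FRZB at log2 changes of 3.82 without extraocular 2 and 2.20 without extraocular 3. DIO2, which activates thyroid hormone, rose 4.25-fold, and OSR2, a transcription factor of craniofacial development, 4.31-fold. TSHR, the thyrotropin receptor, rose by 2.40 on the log2 scale (adjusted p = 0.0196), but its call ended without extraocular 3 (log2 change 1.59), limb 6 (2.44) or limb 12 (2.33), and it was at 3.21 without extraocular 2. With offsets 4 times smaller and larger TSHR was at 3.45 and 1.24 and EN1 at -3.14 and -1.22, as the mean of 1 group lay below the offset for each. The larger offset gave 2.30 for FRZB, 1.47 for OSR2, 1.57 for OMD, -2.09 for SMYD2 and -1.24 for PFKFB1, and the mean of probe sets 1.46 for DIO2 and -1.58 for SMYD2. Among matrix genes, FBLN1, a fibulin, rose 6.82-fold, MGP, matrix Gla protein, 4.76-fold, and OMD, osteomodulin, 4.51-fold. Lower in extraocular muscle were EN1, a homeobox gene of limb patterning (log2 change -2.29), RPL3L, the striated-muscle form of a ribosomal protein (4.64-fold), SMYD2, a lysine methyltransferase (6.43-fold), and PFKFB1, an enzyme that sets fructose-2,6-bisphosphate (4.39-fold).

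CKM, GAPDH and ALDOA were among the largest rises, but their limb arrays were far apart. A rise shared by the glycolysis genes is argued against by the other 14 members of that list, FBP2 and GPD1 included. Their median log2 change was -0.45 (SD 1.49 over genes), against 3.12 for ALDOA, the smallest of the 3 (2.46 without limb 6 and 4.22 without limb 12). The limb arrays of the 6 probe sets of CKM, GAPDH and ALDOA spanned a median of 4.34 on the log2 scale. This was above the 95th percentile of 1.42 for 920 probe sets as bright in extraocular muscle. That spread prompted the test, so it cannot show that saturation was its origin. Signals lost on limb 5 and 6 in saturated probe sets may be 1 reason, but 1 other bright probe set, of PVALB, was as far apart, and PFKM of the glycolysis list stayed at 24132.9 to 26940.2 on the limb arrays. A difference between the muscles would not by itself set arrays of the same muscle apart, so it leaves that range unexplained. Saturation stays open, and so does whether these transcripts differ between the muscles. The sizes of the 3 rises cannot be taken as measured.

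Immediate early genes were higher in extraocular muscle, mainly on extraocular 3. Without that array the list's adjusted p was 0.539 (range over the alternatives 3.20e-19 to 0.597), so the list's call rested on it. The test of single called genes without extraocular 3 had 1 extraocular array, with its spread taken from the limb arrays. It cannot decide whether extraocular 3 alone raised them. Without that array the log2 changes of FOS and GADD45A were 1.94 and 1.70. On extraocular 2 FOS was at 867.8 against 100.3 to 214.3 on the limb arrays, and GADD45A at 1080.6 against 160.5 to 318.6. The calls of both, made with all arrays, ended without limb 6 (3.38 and 2.81) or limb 12 (3.66 and 2.49). A response to collection at autopsy rather than at biopsy could also raise these genes, and cannot be told apart from the muscle, since 0 of the muscle groups held both types of collection. A difference between the muscles themselves stays open, untested.

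Nerve markers had the largest median rise among the cell type lists. The filter on low signals favours such a rise, since 3 of the 9 markers that passed it reached its level on limb arrays, so the tests used the 12 markers measured without a filter. A lower share of muscle fibres would raise the markers of all other cells alike. The nerve list exceeded 80 genes of 6 other marker lists pooled by 1.22 in median log2 change (permutation test over genes for the largest gap of any list, p = 4e-05 with 100000 resamples; genes are not independent). By the same permutation test the gap was 0.47 without extraocular 2 (p = 0.26) and 1.96 without extraocular 3 (p = 9e-05). It rested on extraocular 2, so a lower share of muscle fibres cannot be told apart from a rise of nerve markers alone. Of the 12 markers, 8 were higher on both extraocular arrays than on every limb array. More nerve tissue in the extraocular specimens would give this too, but the list was singled out for its rise, so the count restates the rise and that explanation stays open. NEFM, a neurofilament, was at 8149 on extraocular 2 and 264.9 on extraocular 3. Whether the rise comes from the dense innervation of eye muscles or from where the specimens were taken was not tested.

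Splits of the 5 arrays into 2 and 3 number 10, too few for a share under 0.05. The real split called 759 genes in limma and 1 of the 10 splits, the real one, called as many. The highest other called 0, with up to 772 genes at an unadjusted p under 0.05 against 2109. For genes at least 2-fold apart in all pairings, the real split gave 250 and the highest other 36, again 1 of 10 as large. Every other split mixed extraocular and limb arrays in at least 1 group, so a difference between the muscles widened the spread within it. The low counts of those splits are therefore no reference for chance.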
